A study of Mus musculus with 6 samples.

How the data were processed

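Mammary gland RNA from 3 wild type and 3 LH transgenic pools was measured on 6 Affymetrix mouse arrays. Per the labels, each pool held RNA from 3 mice, 9 mice per group, and double-stranded cDNA primed with oligo-dT was transcribed into biotin-labelled cRNA. The pools of a group came from different mice, so the spread between arrays holds differences between pools as well as technical error. The group came from the source name in the labels, and replicate numbers are names only. Nothing in the labels pairs arrays or names a batch.

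The authors deposited one intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. The version of that software, its detection calls and the genome build are not given in the sources used here, and no positions are reported. The deposited table held 12488 probe sets, all with values above 0. Trimming 2% at each end left a mean of 1500.8 or 1500.9 on each array, and because the arrays did not differ by 10% or more the values were used as deposited. MAS5 scales every array to one target, so a shift of most genes in one direction would not show in these values.

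The platform annotation gave 1 gene for 10833 probe sets (8251 genes), several genes for 396 and none for 1193, besides 66 control probe sets. Genes were named only from probe sets with 1 gene. Gene identifiers were looked up in a table of the GRCm38.p6 assembly, where 10817 of the 10833 were found, and 0 symbols were changed. Symbols can still be old, since the annotation is.

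From the deposited values, log2(signal + 80.0) was computed, where 80.0 is the 20th percentile of all values, so that fold changes of dim genes are understated. Probe sets with a mean signal of at least 336.0, the 40th percentile of the means over the 6 arrays, were tested, which left 7453. The test was limma (lmFit and eBayes with a trend) without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. At that threshold 1586 probe sets changed, 781 higher and 805 lower. Without wild type pool 1 or 3, 1056 and 941 changed. For the gene table the probe set with the highest mean stood for its gene, and p-values were adjusted again over 5731 genes.

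Before the data were examined, 32 gene lists were fixed for mammary biology, cell types and other tissues. The 29 lists with 5 or more tested members were tested with camera at a preset correlation of 0.01, with the correlation estimated, and with fry. List means per array were compared by two-sided exact permutation, whose smallest p is 0.1 for 3 arrays against 3. Named genes followed a rule fixed at the same time. It took the 12 largest changes in each direction among called genes whose groups do not overlap, up to 4 called members per list by size, up to 2 by p where none was called, and 10 genes always (Lhcgr, Esr1, Pgr, Prlr, Csn2, Wap, Krt18, Krt14, Adipoq and Acta1). Kdm5d, Uty, Eif2s3y, Pdgfra, Dcn, Csf1r, Adgre1 and the genes of the closing observations were chosen after their values were seen.

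The fit was tested on simulated data with the means and spread of the LH transgenic against wild type comparison over 7453 probe sets, with 50 probe sets changed at each of 4 sizes. It recovered 30% at 1.5-fold, 80% at 2-fold, 96% at 3-fold and 100% at 4-fold, and 9 of 162 calls (5.6%) were false. Smaller changes were therefore often missed in this simulation with 3 arrays per group. It changed a smaller share of probe sets than the 21.3% called in the data. The Benjamini-Hochberg threshold depends on that share, so recovery in the data may differ.

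The other settings were quantile normalization, median centring, trimmed-mean scaling, other pseudocounts (a floor at 16.8 with none added, or 325.5), no filter, a stricter filter (mean of at least 933.0), eBayes without a trend, robust eBayes, arrayWeights, the skeletal muscle or the B and T cell list mean per array as a covariate, the mean of all probe sets of a gene, leaving out each array, and the estimated correlation for lists. A further alternative, added after the data were seen, divided each array by the mean level of its 9 bacterial hybridisation controls. Software was R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The 66 control probe sets were left out of the tests and described separately.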

Results

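RNA abundance was measured in thoracic mammary glands of virgin mice of an F1 CF-1/FVB background, 16 weeks old. Transgenic mice that overexpress luteinizing hormone (LH), the pituitary hormone that stimulates the gonads to make sex steroids, were compared with wild type mice. Each group held 3 Affymetrix arrays, and each array was hybridised with RNA pooled from 3 mice, so that 18 mice were used in all. The deposited signal had a trimmed mean of 1500.8 or 1500.9 on every array, with a median between 540.6 and 583.4. The 100 brightest probe sets held 16.0% to 18.0% of the summed signal on the wild type arrays and 19.8% to 21.5% on the LH transgenic arrays. Precision is limited by the number of arrays. Values are mean signal ± SD over the 3 arrays of a group, and log2 differences are LH transgenic minus wild type on the log2(signal + 80.0) scale.

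The single comparison of the design asks which genes differ in the mammary gland between LH-overexpressing and wild type virgin mice. In the LH transgenic glands, lists of milk and alveolar genes, macrophage markers (6 of 13 members called) and cell division genes (8 of 29) were higher by camera with the preset correlation. They were not called with an estimated correlation (adjusted p = 0.447, 0.447 and 0.522). With the bacterial controls as the scale, which lowers every LH transgenic value, the medians of the last 2 lists lay below 0. The median of all genes was -0.638 on that scale, and both lists kept their camera calls. Lists of fat cell, endothelial, fibroblast and matrix, and skeletal muscle genes were lower with the preset correlation, and not with the estimated correlation (adjusted p = 0.106, 0.106, 0.497 and 0.547). Muscle genes were lower in LH transgenic pools 1 and 2, while pool 3 (list mean 0.48) lay near the wild type pools (0.58 to 0.75). Of 5731 genes tested with limma, 1282 (22.4%) changed at a Benjamini-Hochberg adjusted p under 0.05, 585 of them higher and 697 lower. At least 2-fold changes were found in 380 genes, 144 higher and 236 lower. The signals of the groups did not overlap for 2331 genes (40.7%, where chance gives 10%). Array profiles correlated across genes at 0.955 to 0.974 within groups and at 0.897 to 0.924 between them, and genes are not independent replicates in these correlations. The first principal component held 60.4% of the variance. Without wild type pool 3, 747 genes changed, 314 higher and 433 lower, and without wild type pool 1 or LH transgenic pool 1 the genes called higher numbered 379 and 389. Scaling to the bacterial hybridisation controls, a choice made after the data were seen, moved the median of all genes from 0.009 to -0.638, and 98 of 3283 called genes (3%) were then higher against 45.6% of the 1282 above. On that scale the differences of Acta2, Jak2, Psmb8, Pdk4, Erbb3, Rps28, Rps24 and Rps7 turned below 0, and 30 of 105 named genes lost their calls, among them Csn2, Foxm1, Mki67, Plk1, Lyz2, C1qa, Ctss and Xbp1. With the skeletal muscle level or the B and T cell level as a covariate, 608 and 752 genes changed, and a larger pseudocount left 154 genes at least 2-fold lower.

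**Figure D1:**
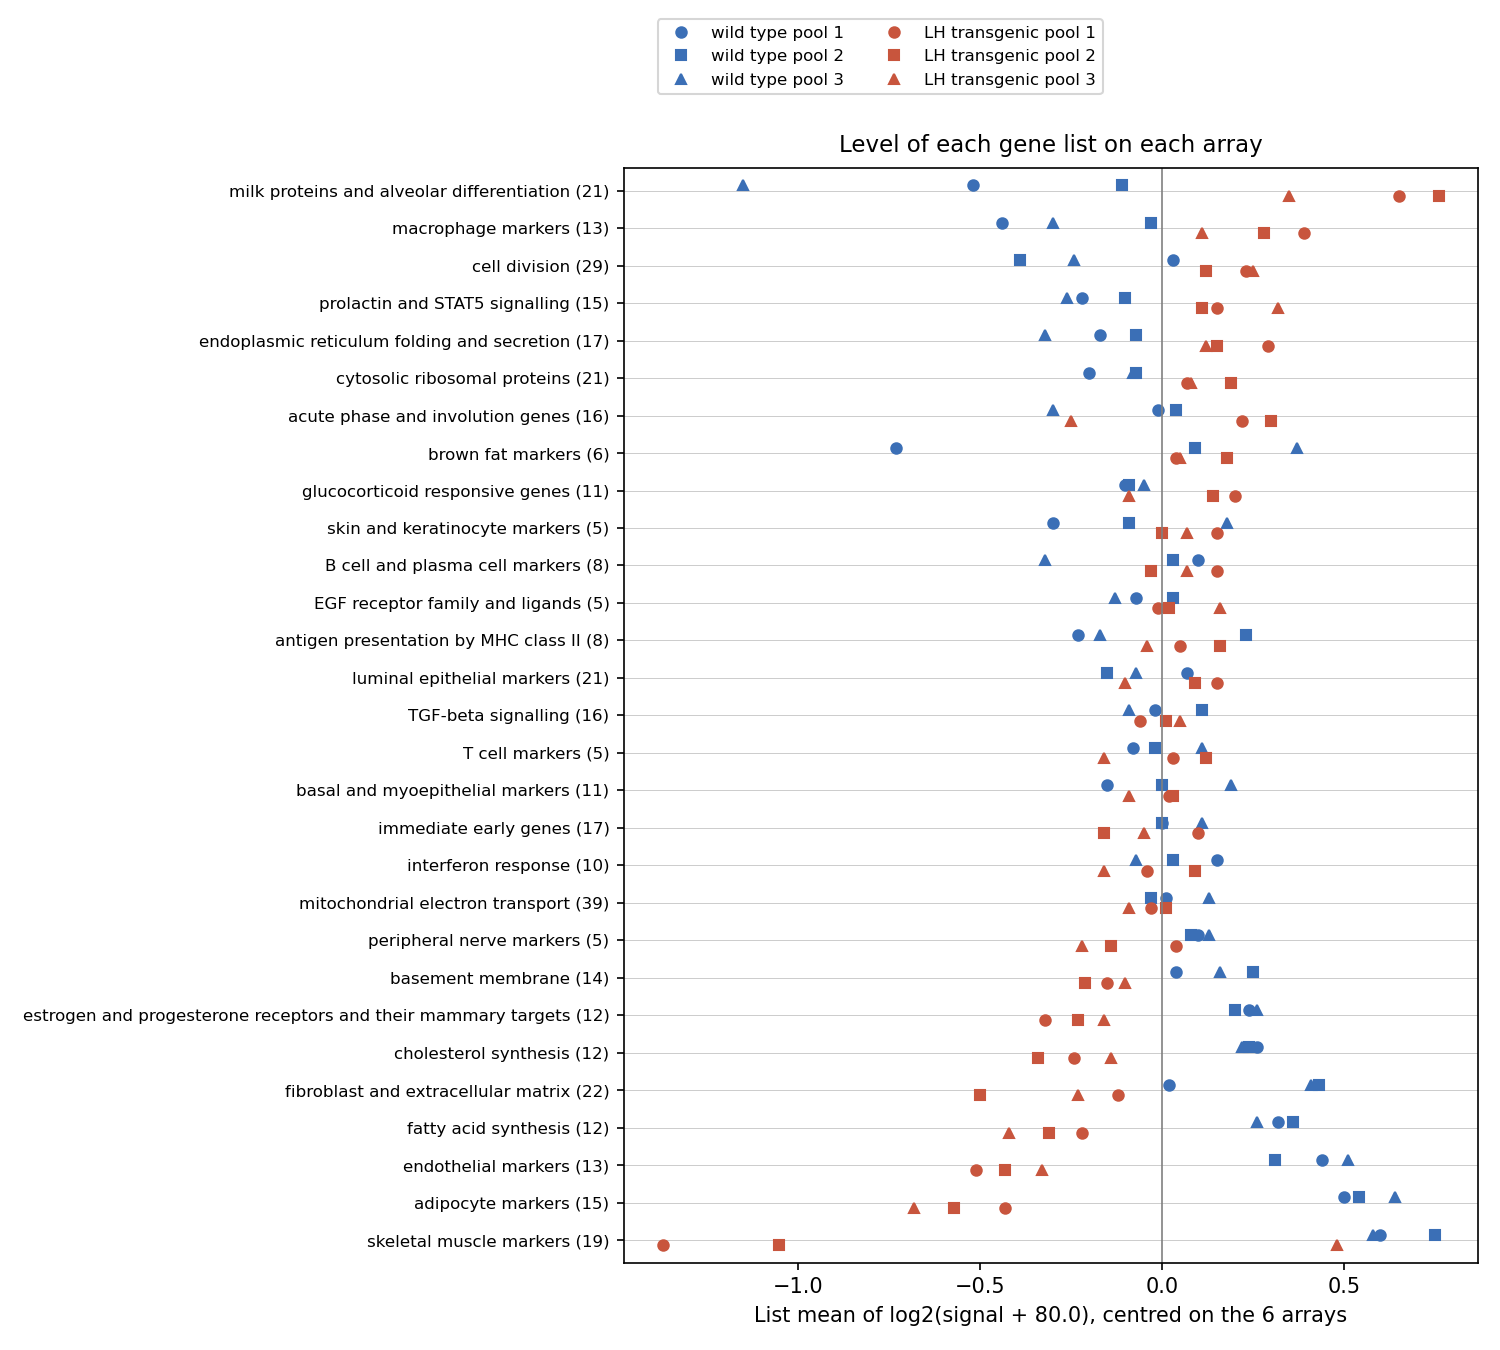
Mean log2(signal + 80.0) of the tested members of each gene list on each of the 6 arrays, centred on the mean of the arrays, with the number of genes in brackets, wild type pools in blue and LH transgenic pools in red. Milk and alveolar genes were between -1.15 and -0.11 in wild type pools and between 0.35 and 0.76 in LH transgenic pools, and skeletal muscle markers were at 0.48 in LH transgenic pool 3 against -1.37 and -1.05 in the other pools of that group.

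The 12 genes with the largest increase among changed genes without overlap between groups included the milk genes Csn1s2b and Glycam1. Ctse, an aspartic protease of the endosome, rose from 471.6 ± 99.9 to 4518 ± 211 (log2 3.07, SE 0.16, adjusted p 2.65e-05). Fabp3, a fatty acid binding protein of heart and lactating mammary gland, rose from 4831 ± 3438 to 34177 ± 9826 (log2 3.04, adjusted p 0.0024). Xist, the RNA that silences the inactive X chromosome, rose from 745.9 ± 318.9 to 6094 ± 2354 (log2 2.92, adjusted p 0.000686). The Y-linked genes Kdm5d, Uty and Eif2s3y had signals of at most 70.0 on every array. The homeobox gene Rhox5 (3.02), the casein gene Csn1s2b (2.84), Snw1 (2.65), the serum amyloid gene Saa3 (2.46), Glycam1 (2.16), the MHC class II gene H2-Ea (2.16), Rbfox2 (2.09) and the actin-binding protein gene Cotl1 (2.04) completed the list with D17H6S56E-5 (3.58). D17H6S56E-5 had a wild type SD of 6214 around a mean of 3979, as pool 2 had 11154.8 against 375.0 and 407.9 in pools 1 and 3, and its call was lost under 9 of 19 other settings. Its difference was 2.80 without wild type pool 1, 5.11 without wild type pool 2 and 2.85 without wild type pool 3. Fabp3 had 2.43 without wild type pool 3, H2-Ea 2.76 without wild type pool 2 and Csn1s2b 3.46 without LH transgenic pool 3. Wild type pool 2 stood out for H2-Ea too (972.7 against 221.1 and 221.0 in pools 1 and 3). The same held for the MHC class II gene H2-Eb1 (2567.3 against 756.9 and 755.5), and the cause was not tested.

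Among the 12 genes with the largest decrease, Ces1d, a carboxylesterase of fat cells and liver, fell from 16464 ± 1724 to 2158 ± 454 (log2 -2.90, SE 0.16, adjusted p 3.4e-05). Cited1, a transcriptional co-regulator of estrogen-responsive mammary epithelium, fell from 6859 ± 1811 to 1019 ± 188 (log2 -2.63, adjusted p 0.000147). Itih2 (-2.88), Kcnk2 (-2.30), Dmtn (-2.27), Gstm2 (-2.24), Amy1 (-2.23), Ifi27l2a (-2.20), Enpep (-2.20) and the muscle genes Myh4 (-2.13) and Atp2a1 (-2.10) also fell. The probe sets of Actb disagreed. The probe set that represents Actb in the gene table fell by 2.66 (3.29 without LH transgenic pool 2), from 3060 ± 973 to 511.6 ± 488.2. A second had a difference of 0.32 (adjusted p 0.645). The 3 Actb control probe sets, left out of the tests, were brighter, with wild type means of 19088 to 40306. They were higher by 1.04, 1.49 and 1.69 on the log2 scale, so the place of Actb among these 12 rests on 1 dimmer probe set. Of 881 genes with several tested probe sets, 322 had a call, and Krt17, Nfix, Noct, Peg3 and Wnk1 were called in both directions by different probe sets.

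Of 21 tested genes of milk proteins and alveolar differentiation, 16 rose, 20 when adjusted over the list alone, and none fell, with a median log2 difference of 0.99. Csn1s2b rose from 412.9 ± 291.2 to 3530 ± 1990, Glycam1, a mucin of milk, from 20747 ± 11956 to 84770 ± 14855, and Cel, a lipase secreted into milk, from 10658 ± 4078 to 38778 ± 8818. The folate receptor gene Folr1 rose from 4236 ± 2195 to 12836 ± 2978. Wap, whey acidic protein, rose from 34962 ± 21321 to 95087 ± 17283 (log2 1.61, adjusted p 0.0129), and Csn2, beta-casein, from 40554 ± 6247 to 74506 ± 2452 (log2 0.89, adjusted p 0.00181). The list was higher by camera (adjusted p 4.76e-10), but not with an estimated correlation (adjusted p = 0.447), and the wild type pools themselves ranged from -1.15 to -0.11 in list mean. With the bacterial controls as the scale, the median was 0.31 and 8 members rose. Skeletal muscle markers were lower in the same comparison (median log2 -1.43). With their level as a covariate, in a fit with 3 residual degrees of freedom, the milk list stayed higher by camera (median 0.93, adjusted p 5.13e-06), but 6 members were called and the mean of the list had an SE over arrays of 0.55 against 0.33 without it. Wap (1.66, SE 0.59), Cel (1.52, SE 0.43), Folr1 (1.36, SE 0.56) and Fabp3 (2.61, SE 0.73) lost their calls. Without the covariate their differences were 1.61, 1.91, 1.71 and 3.04, with SE of 0.37, 0.29, 0.36 and 0.47. Csn1s2b lost its call too, and its difference went from 2.84 (SE 0.54) to 1.61 (SE 0.66).

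**Figure D2:**
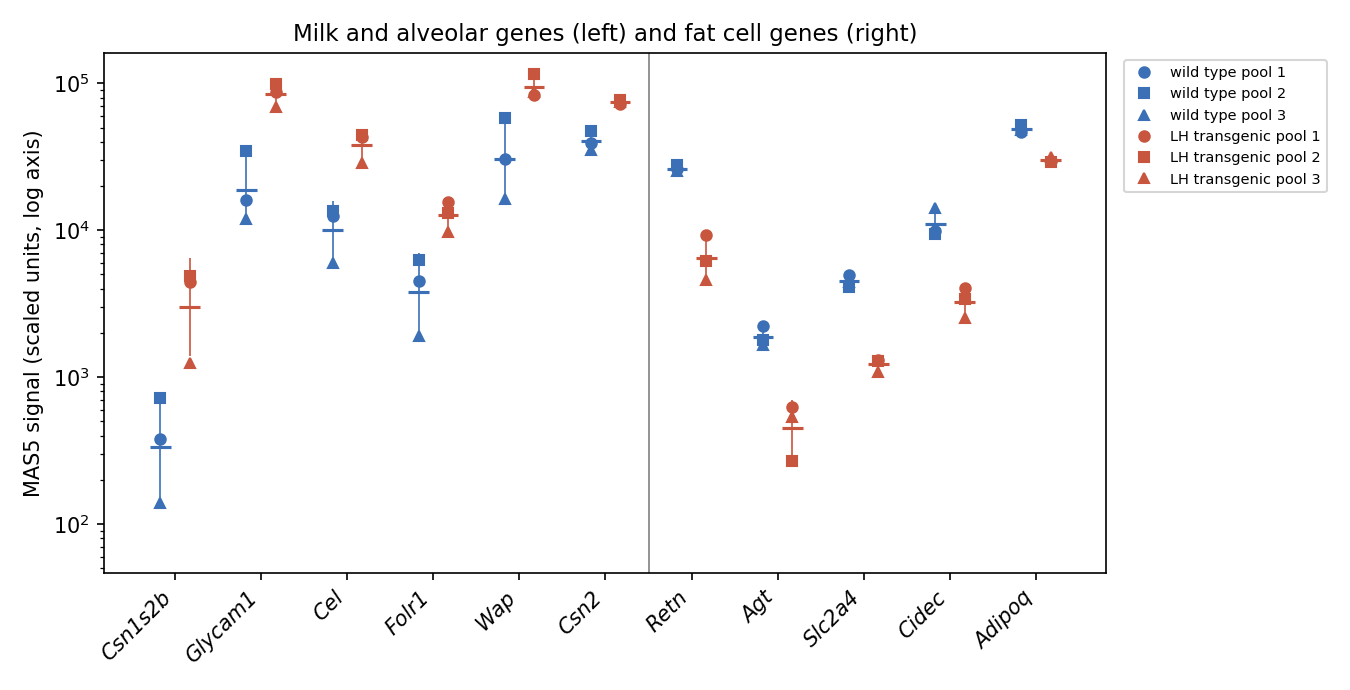
Signal of 6 milk and alveolar genes and 5 fat cell genes in each pool, on a log axis, with points for the 3 wild type (blue) and 3 LH transgenic (red) pools, horizontal lines for geometric means and vertical lines for 1 SD of the log2 values. Every LH transgenic pool lay above every wild type pool for Wap and below it for Retn.

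Genes of prolactin and STAT5 signalling rose in 7 of 15 tested members, and none fell, 9 and 1 when adjusted over the list alone (median log2 0.50, but -0.19 with the bacterial controls as the scale). Elf5, a transcription factor of alveolar cells, rose from 14548 ± 5268 to 32407 ± 5590, and Id2 from 6386 ± 1597 to 13725 ± 5089. Claudin Cldn3 rose from 6629 ± 785 to 11540 ± 1450. Jak2, the kinase of the prolactin receptor, rose from 1184 ± 80.1 to 1907 ± 486, a call lost under 7 of 19 other settings. The list was higher by camera (adjusted p 0.0144) and not with an estimated correlation (adjusted p = 0.326). Without wild type pool 1 or 3, 3 and 2 members rose.

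Luminal and basal epithelial markers moved in both directions. Of 21 luminal markers 6 rose and 3 fell (7 and 4 adjusted over the list alone; camera adjusted p 0.259), and Krt18, a keratin of luminal cells, was 13208 ± 1081 in wild type and 13650 ± 1931 in LH transgenic glands (adjusted p 0.87). The transcription factor Ehf rose from 481.4 ± 141.8 to 1491 ± 205 and Cldn3 by 0.79, whereas Prom1 (-1.68) and the estrogen receptor cofactor Foxa1 (-1.23) fell. Without wild type pool 2, 3 luminal markers rose. Of 11 basal and myoepithelial markers 1 rose and 1 fell, 2 and 1 adjusted over the list alone (camera adjusted p 0.715), these being the smooth muscle actin gene Acta2 (0.66) and Lgals7 (-1.57). The list of estrogen and progesterone receptors and their mammary targets had 12 tested members, of which 4 fell and 1 rose (6 and 1 adjusted over the list alone; median log2 -0.45; camera adjusted p 0.0475). Cited1, Igf1 (-1.18) and Id4 (-1.10) were among those that fell, and Xbp1 rose by 0.79. The call of this list was lost under 11 of 20 other settings, including the estimated correlation (adjusted p = 0.361). Esr1, Pgr and Krt14, with highest signals of 417.9, 206.3 and 161.4, lay below the filter on dim probe sets and were not tested. Lhcgr and Prlr had 0 probe sets annotated to them alone and were not analysed here, so the lists that name them were tested without them.

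Of 15 tested adipocyte markers 13 fell, 13 also when adjusted over the list alone, and none rose (median log2 -1.22; camera adjusted p 1.34e-09; adjusted p = 0.106 with an estimated correlation). The hormone gene Retn fell from 26317 ± 1233 to 6704 ± 2402, the angiotensinogen gene Agt from 1898 ± 309 to 476.1 ± 183.8, the insulin-responsive glucose transporter gene Slc2a4 from 4509 ± 462 to 1225 ± 129, and the lipid droplet gene Cidec from 11191 ± 2638 to 3306 ± 757. Adipoq, adiponectin, fell from 48797 ± 2582 to 30148 ± 1314 (log2 -0.69, adjusted p 0.00231), a call lost at an adjusted p of 0.0501 with the skeletal muscle level as a covariate, where the difference was -0.61 and its SE 0.16 against 0.11. The adipocyte list kept its call there (median -1.16, adjusted p 3.16e-10). With the bacterial controls as the scale 15 of 15 members fell, but so did 3185 of all 3283 genes called on that scale.

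Of 12 genes of fatty acid synthesis 6 fell and none rose (7 fell and 1 rose adjusted over the list alone; median log2 -0.40; camera adjusted p 0.00156; adjusted p = 0.326 with an estimated correlation). The elongase gene Elovl6 fell from 10616 ± 1177 to 2778 ± 1150, Me1 from 18974 ± 1323 to 6188 ± 415, and Pcx (-1.22) and Scd2 (-1.11) fell as well. Of 12 genes of cholesterol synthesis 4 fell, 6 when adjusted over the list alone, and none rose (median log2 -0.48; camera adjusted p 0.00372; adjusted p = 0.265 with an estimated correlation). These were Nsdhl (-0.99), Dhcr7 (-0.72), Hmgcs1 (-0.68) and Lss (-0.66), of which Dhcr7, Hmgcs1 and Lss lost their calls under 4 of 18, 10 of 19 and 7 of 18 other settings. With the skeletal muscle level as a covariate the cholesterol list was not called (adjusted p 0.0542), with a median of -0.39 against -0.48. Without wild type pools 1, 2 or 3 or LH transgenic pool 2, 2, 1, 1 and 2 of its members fell.

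Of 13 endothelial markers 10 fell, 12 when adjusted over the list alone, and none rose (median log2 -0.82; camera adjusted p 1.85e-06; adjusted p = 0.106 with an estimated correlation). Ramp2 fell from 4521 ± 171 to 1759 ± 162, Emcn from 2915 ± 341 to 1153 ± 323, Eng from 12843 ± 2344 to 5275 ± 840, and Vwf, von Willebrand factor, from 2994 ± 327 to 1344 ± 218. Of 22 fibroblast and matrix genes 12 fell, 15 when adjusted over the list alone, and none rose (median log2 -0.70; camera adjusted p 5.03e-06; adjusted p = 0.497 with an estimated correlation). The collagen genes Col6a3 (-1.16), Col5a1 (-1.14) and Col5a2 (-1.13) and the elastin gene Eln (-0.92) fell, while Pdgfra, a receptor of fibroblasts, and Dcn, a matrix proteoglycan, had differences of -0.03 and -0.10 and were not called. Of 14 basement membrane genes 4 fell and 2 rose (7 and 2 adjusted over the list alone; median log2 -0.27; camera adjusted p 0.0396; adjusted p = 0.447 with an estimated correlation). Nid2 (-1.12), Lama4 (-1.01) and Col4a2 (-1.01) fell, Lamb3, a laminin chain of epithelia, rose by 1.24, and the call of the list was lost under 6 of 20 other settings.

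Of 13 tested macrophage markers 6 rose, 8 when adjusted over the list alone, and none fell (median log2 0.60, but -0.08 with the bacterial controls as the scale; camera adjusted p 0.00156; adjusted p = 0.447 with an estimated correlation). Lysozyme Lyz2 rose from 8339 ± 2312 to 16602 ± 1084, Mpeg1 from 3089 ± 999 to 6093 ± 1148, the complement gene C1qa from 6272 ± 2055 to 11858 ± 1401, and the protease gene Ctss from 7549 ± 1368 to 14414 ± 1428. The receptor genes Csf1r (0.09) and Adgre1 (0.24) were not called. With the skeletal muscle level as a covariate the list was not called (adjusted p 0.0936) and its median was 0.32. Of 8 B cell and plasma cell markers Blnk rose (1.15) and no other was called, 1 also when adjusted over the list alone (camera adjusted p 0.715). None of 5 T cell markers was called by limma, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p 0.827), with differences of -0.65 for Thy1 and 0.22 for Lef1. Of 8 genes of antigen presentation by MHC class II 2 rose and none fell (2 and 1 adjusted over the list alone; camera adjusted p 0.893), namely H2-Eb1 (1.72) and Ctss, and the list's median was -0.18 and its mean 0.11.

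Cell division genes rose in 8 of 29 tested members, 13 when adjusted over the list alone, and none fell (median log2 0.37, but -0.25 with the bacterial controls as the scale, where all genes had -0.638; camera adjusted p 0.000169; adjusted p = 0.522 with an estimated correlation). Foxm1, a transcription factor of dividing cells, rose from 2130 ± 425 to 4747 ± 251, Mki67, the proliferation antigen, from 1280 ± 268 to 2657 ± 478, Mad2l1 from 982.8 ± 319.4 to 1847 ± 371, and the mitotic kinase gene Plk1 from 878.3 ± 128.8 to 1636 ± 131. Without wild type pool 2, wild type pool 3 or LH transgenic pool 1, 5 members rose each time. Genes of endoplasmic reticulum folding and secretion rose in 6 of 17 members and 1 fell (8 and 1 adjusted over the list alone; median log2 0.45, but -0.23 with the bacterial controls as the scale; camera adjusted p 0.013; adjusted p = 0.447 with an estimated correlation). P4hb (1.25), Ssr1 (0.79), Xbp1 (0.79) and Sec61a1 (0.71) rose, P4hb and Ssr1 losing their calls under 8 and 7 of 19 other settings. The list was not called with the skeletal muscle level as a covariate (adjusted p 0.161, median 0.33), and 3 members rose without wild type pool 3 or without LH transgenic pool 1. Cytosolic ribosomal protein genes rose in 7 of 21 members and 1 fell (12 and 1 adjusted over the list alone; median log2 0.34, but -0.35 with the bacterial controls as the scale; camera adjusted p 0.00158; adjusted p = 0.522 with an estimated correlation). Rps28 (0.63), Rps24 (0.54) and Rps7 (0.51) rose and Rpl22 fell by 0.68. The ribosomal list was not called after quantile normalization (adjusted p 0.803), where its median was 0.01, 1 member rose and 1 fell, and Rps24 and Rps7 differed by 0.09 and 0.25. It was not called either with the skeletal muscle level as a covariate (adjusted p 0.0542, median 0.30). Of its members, 1 rose without wild type pool 3, 3 without wild type pool 1 or LH transgenic pool 2, and 4 without LH transgenic pool 3. Of 39 genes of mitochondrial electron transport 2 fell, Sdha (-0.81) and Sdhb (-0.41), and none rose (1 and 0 adjusted over the list alone; camera adjusted p 0.577).

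Skeletal muscle markers were lower in LH transgenic pools 1 and 2, while pool 3 lay near the wild type level. Of 19 tested members 10 fell, 14 when adjusted over the list alone, and none rose (median log2 -1.43; camera adjusted p 6.11e-06; adjusted p = 0.547 with an estimated correlation). List means per array were 0.60, 0.75 and 0.58 in wild type pools 1, 2 and 3, and -1.37, -1.05 and 0.48 in LH transgenic pools 1, 2 and 3 (two-sided exact permutation p 0.1, the smallest that 3 arrays against 3 allow). Myh4, a fast myosin heavy chain, was 11741 ± 966 in wild type and 3786 ± 4065 in LH transgenic glands, and the calcium pump gene Atp2a1 was 19832 ± 2284 and 5748 ± 5009. Pygm (-1.94) and Tnnt3 (-1.92) fell too. Acta1, skeletal actin, was 30190 ± 3163 and 16540 ± 13871 and was not called (log2 -1.17, adjusted p 0.0816). Without LH transgenic pool 1 or 2, 4 and 5 of 19 members fell, with medians of -0.91 and -1.0, and without wild type pool 1, 2 or 3, 6, 6 and 5 fell. Without LH transgenic pool 3, 17 of 19 fell, with a median of -1.89, Acta1 was called (-1.81, adjusted p 0.000198), and Myh4 and Atp2a1 differed by -2.96 and -2.76, Pygm and Tnnt3 by -2.62 and -2.57. The calls of Myh4, Pygm and Tnnt3 were lost under 8, 5 and 3 of 19 other settings.

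**Figure D3:**
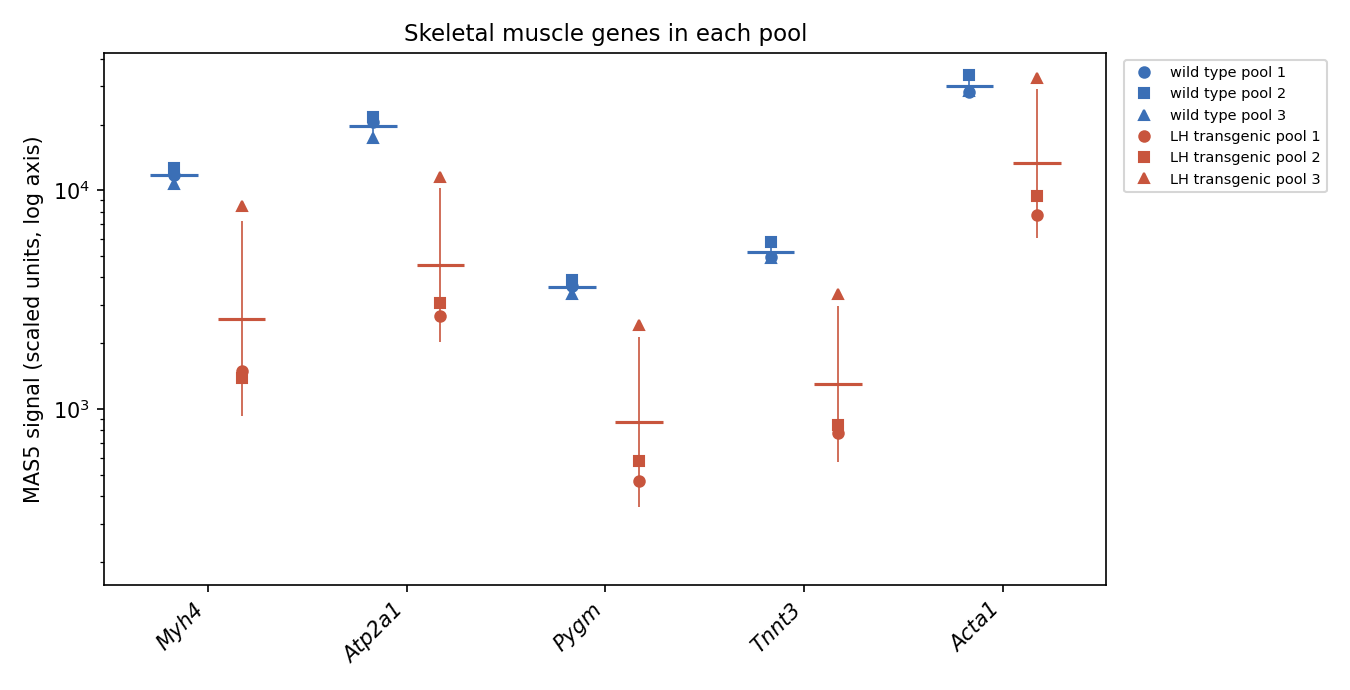
Signal of 5 skeletal muscle genes in each pool, on a log axis, with points for the 3 wild type (blue) and 3 LH transgenic (red) pools, horizontal lines for geometric means and vertical lines for 1 SD of the log2 values. LH transgenic pool 3 lay above pools 1 and 2 for each of the 5 genes.

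Of 6 brown fat markers Fabp3 rose and Cox8b fell (-0.95), 1 and 1 also when adjusted over the list alone (camera adjusted p 0.827; median log2 -0.13, mean 0.18). Of 5 peripheral nerve markers Sox10 rose (0.76) and Pmp22 fell (-1.40), 2 and 2 adjusted over the list alone (camera adjusted p 0.827). No skin marker of 5 was called by limma, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p 0.715), with differences of 0.29 for Lor and 0.25 for Krt10. The salivary gland list had 1 tested member, Amy1, which fell from 6960 ± 1093 to 1408 ± 79.3. Of 3 tested red blood cell markers none was called by limma (0 at an unadjusted p under 0.05), and Hba-a1 was 32299 ± 10412 and 23086 ± 4508. Of 3 tested genes of the LH receptor and steroid synthesis list none was called by limma (0 at an unadjusted p under 0.05), with differences of 0.23 for Nr5a1 and 0.06 for Fshr. These 3 lists had too few members for a set test.

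Of 16 acute phase and involution genes 5 rose and 3 fell, 7 and 4 adjusted over the list alone (camera adjusted p 0.577), and 5 fell without LH transgenic pool 2. Saa3 rose from 1142 ± 432 to 6966 ± 3426 and Lbp, which binds bacterial lipopolysaccharide, from 6337 ± 1067 to 14429 ± 4248, while Orm1 fell from 4179 ± 420 to 1249 ± 485 and the haptoglobin gene Hp from 10114 ± 1584 to 4367 ± 1799. Of 17 immediate early genes 2 rose and 4 fell, also when adjusted over the list alone (camera adjusted p 0.752), with Jund (1.15) and Junb (0.84) higher and Klf4 (-0.84) and Dusp1 (-0.83) lower, but 1 fell without wild type pool 1 or 3 or LH transgenic pool 1 or 2. Of 16 TGF-beta signalling genes 3 rose and 2 fell, also when adjusted over the list alone (camera adjusted p 0.893), Id2 (1.07) and Tgfb2 (1.04) being higher and Id3 (-1.21) and Id1 (-1.08) lower, and 4 fell without LH transgenic pool 3. Of 11 glucocorticoid responsive genes 3 rose, 4 when adjusted over the list alone (camera adjusted p 0.563), the metallothionein genes Mt1 (0.76) and Mt2 (0.74) and Pdk4 (0.56), whose calls were lost under 10, 9 and 7 of 19 other settings. Of these genes 0 or 1 rose when any array but LH transgenic pool 3 was left out. Of 10 interferon response genes Psmb8 rose (0.48) and Ifi27 fell (-0.66), 1 and 1 also when adjusted over the list alone (camera adjusted p 0.799). Of 5 genes of the EGF receptor family Erbb3 rose (0.54), 1 also when adjusted over the list alone (camera adjusted p 0.715).

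Control probe sets gave the signs of RNA quality and hybridisation. The log2 ratio of 3′ to 5′ control signal for Gapdh was 0.29 ± 0.14 in wild type and 0.22 ± 0.24 in LH transgenic arrays (two-sided exact permutation p 0.6), and for Actb it was 1.09 ± 0.07 and 0.64 ± 0.37 (p 0.2 by the same exact test). The 9 bacterial hybridisation controls were higher on the LH transgenic arrays by a mean of 0.69 on the log2 scale (1.61-fold, range 0.46 to 0.91), with each LH transgenic array above each wild type array for all 9 (exact permutation p of their mean 0.1, the smallest possible). Gapdh control probe sets differed by 0.09 to 0.29, less than the bacterial controls, and the 3 Actb control probe sets by 1.04, 1.49 and 1.69, more than their mean. Among genes named above, the calls of Psmb8, Klf4, Sdhb, Cox8b and Mad2l1 were lost under 9, 8, 8, 6 and 6 of 19 other settings, and those of H2-Eb1, Ifi27, Rps28 and Wap under 3. Where a list had 0 to 2 calls in a direction, leaving out single arrays moved that count by at most 1, apart from the TGF-beta list. By camera 14 of 29 lists tested were called with the preset correlation, 6 higher and 8 lower. With an estimated correlation 0 were called and 3 had an unadjusted p under 0.05. Among the 14 lists the estimates ran from -0.043 (estrogen and progesterone) to 0.877 (skeletal muscle). For cholesterol (-0.02) and for estrogen and progesterone the estimates lay below the preset 0.01, so a higher correlation between their genes was not why these calls were lost. The estimates of the prolactin and STAT5 (0.016) and endothelial (0.017) lists lay close to the preset. What else made the settings differ was not tested, so a lost call is not by itself a sign of correlated genes. The test fry, which asks whether a list moves one way without comparing it with other genes, called 10 lists, all among the 14. It did not call the macrophage (adjusted p 0.0566), fibroblast and matrix (0.0581), cell division (0.0828) or skeletal muscle (0.182) lists.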

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

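All tests of explanations in this part were chosen after the results were seen. Of the control probe sets outside the comparison of genes, 3 kinds stood higher, as means per array, on every LH transgenic array than on every wild type array. The 9 bacterial hybridisation controls differed by 0.69 on the log2 scale and the 15 sense-strand controls, by 0.66. The 3 Actb control probe sets differed by 1.41.

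The higher signal of the bacterial controls may come from LH transgenic arrays that were dimmer before MAS5 scaled them. These controls are RNA added to the hybridisation mix, and scaling a dimmer array up to the common target raises them alike. The 19 bacterial and yeast controls with low signal would rise with dimmer arrays and stay level with unequal amounts of the added controls alone. They differed by 0.42 (SE 0.11, 14 of 19 higher), but their levels per array overlapped between groups, with an exact permutation p of 0.2. The 15 sense-strand controls differed by 0.66 (SE 0.11, 14 of 15 higher). They were among the flagged results and were not used as a test, so the 2 explanations were not told apart here. A lower amount of labelled RNA and a biological drop of most transcripts in the LH transgenic glands were not tested and stay open too.

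The lower skeletal muscle signal of LH transgenic pools 1 and 2 could reflect unequal amounts of muscle carried over when the glands were dissected. Pool 3 was the highest of the 3 LH transgenic pools for 18 of 19 muscle genes, by a median of 1.86 on the log2 scale (SD over genes 0.64) above the mean of pools 1 and 2, while the median of all genes was 0.02, but this restates the fall in pools 1 and 2, and with 1 array per pool the explanation stays open. An effect of the transgene on muscle RNA in every pool cannot be told apart from chance, since the exact permutation p was 0.1, the smallest that 3 arrays against 3 allow, and the list mean of pool 3 lay 0.16 below the wild type mean (-0.16) where the wild type arrays spanned 0.17.

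The rise of milk genes with a fall of fat cell genes was set against array scaling, a lower share of fat cells and a lower share of muscle. If scaling alone were the cause, no milk gene would rise with the bacterial controls as the scale, and 8 of 21 did. A scale factor per array would also move milk and fat cell genes nearly alike. Their list means differed by 2.30 (95% interval over arrays 1.33 to 3.26). The tables therefore argue against array scaling alone for the rise of those 8 and for the gap between the 2 lists. If fat cells alone had become a smaller share, markers of other cell types would rise alike. The mean of the macrophage list exceeded that of the endothelial list by 1.36 (SE over genes 0.16, permutation p over genes 1e-05, the smallest that 100000 permutations give, with genes that are not independent replicates). These lists were picked after being called higher and lower, so the gap restates those calls and is no test of its own. The endothelial list differed by -0.84, with 0.31 to 0.51 in wild type and -0.51 to -0.33 in LH transgenic pools. Other list means were -0.57 for fibroblast and matrix, 0.52 for macrophage, 0.09 for luminal, -0.02 for basal, 0.13 for B cell and -0.01 for T cell markers. They did not rise alike, so the tables argue against a lower share of fat cells alone. A lower share of fat cells as part of the cause stays open. Less muscle RNA alone would move milk and fat cell genes alike, but with the muscle level as a covariate their list means differed by 2.26 (SE over arrays 0.61, 95% interval 0.33 to 4.18, against 2.30 and SE 0.35 without it) and the milk median was 0.93 against 0.99, although calls were lost with 3 residual degrees of freedom, so the tables argue against muscle as the whole cause. A change in macrophages or in endothelial cells themselves stays open, and an effect of the transgene on the gland was not separated from these.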

How the results depend on the processing

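Spike-in scaling was chosen after the data were seen, and the other alternatives were planned. Among the differences of named genes, 9 reversed, all with spike-in scaling: Acta2 (-0.02), Jak2 (-0.03), Psmb8 (-0.21), Pdk4 (-0.11), Erbb3 (-0.14), Rps28 (-0.06), Rps24 (-0.15), Rps7 (-0.18) and Krt18 (-0.65). With it 30 of 105 named genes called lost the call, 7 of them among the 50 below (Acta2, Csn2 at 0.20, Ctss, Foxm1, Mki67, Plk1 and Sec61a1). That scaling lowers every LH transgenic value by construction, and the medians of 5 lists called higher turned below 0 while their camera direction stayed. It gave 3999 changed probe sets (140 higher, 3859 lower), 3283 genes (98 and 3185) and 1187 genes changed at least 2-fold (45 and 1142). Of the 1282 genes called, 791 were called with the same sign by it and 224 had the other sign, as 2 had after quantile normalization, 1 with the muscle covariate and 3 with the mean of all probe sets of a gene.

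The skeletal muscle covariate gave 699 probe sets (305 higher, 394 lower) and 608 genes (259 and 349), and the B and T cell covariate 951 (440 and 511) and 752 (313 and 439). Each spends 1 of the degrees of freedom, leaving 3, and the muscle level partly follows the groups. With the muscle covariate the macrophage list (adjusted p 0.0936, median 0.32 against 0.60) was not called. The skeletal muscle list was not either (0.799), which tests nothing, since its own mean is the covariate. A pseudocount at the 40th percentile left 154 genes at least 2-fold lower by shrinking fold changes. With the estimated correlation no list was called, with adjusted p of 0.447 (milk, macrophage, basement membrane, endoplasmic reticulum), 0.522 (cell division, ribosomal), 0.106 (adipocyte, endothelial), 0.497 (fibroblast and matrix), 0.547 (skeletal muscle), 0.361 (estrogen and progesterone), 0.326 (prolactin and STAT5, fatty acid) and 0.265 (cholesterol). The estrogen and progesterone list also lost its call with quantile normalization (0.0613), median centring (0.0501), no filter (0.108), the stricter filter (0.0527), eBayes without a trend (0.0547), the muscle covariate (0.173), the B and T cell covariate (0.0841) and the mean of all probe sets of a gene (0.252), and so did the basement membrane list with the stricter filter (0.257), the muscle covariate (0.161), the B and T cell covariate (0.0599) and spike-in scaling (0.0941). The ribosomal list lost it with quantile normalization (0.803, median 0.01), the muscle covariate (0.0542, median 0.30 against 0.34) and spike-in scaling (0.602), and the cholesterol (0.0542, median -0.39 against -0.48) and endoplasmic reticulum (0.161, median 0.33 against 0.45) lists with the muscle covariate. The cause was not tested.

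Leaving out each array in turn gave 941 to 1641 probe sets (434 to 745 higher, 507 to 896 lower) and 747 to 1361 genes (314 to 595 higher, 433 to 766 lower). Fewer arrays lower the power, but without LH transgenic pool 3 more genes were called, 1361 against 1282. Power and differences between pools were not separated. The estrogen and progesterone list ranged from 0.0391 to 0.0752 and the basement membrane list from 0.0145 to 0.12. At least 2-fold changes numbered 321 to 423. Of 105 named genes called, 50 kept the call under every planned setting run for them, 24 lost it only with the muscle covariate, and 22 lost it under 3 or more. Trimmed-mean scaling moved nothing and tests nothing. Dim genes are limited by background, since detection calls were not used here.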

Other observations

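All tests in this part were chosen after the results were seen, and the genes named here were picked because they stood out. Gjb6, a gap junction gene, rose from 1169 ± 353 to 4836 ± 1391 with 1 probe set (log2 1.98) and by 2.31 with another, and Gjb2 rose from 12769 ± 2122 to 36777 ± 6096 (log2 1.52, adjusted p 0.000466). The milk transporter gene Abcg2 rose by 1.55, the amino acid transporter gene Slc7a5 by 1.86, the immunoglobulin receptor gene Pigr from 11127 ± 4870 to 41623 ± 3946 (log2 1.99), and Tnfrsf11a, which encodes the receptor RANK, from 286.1 ± 87.1 to 1136 ± 200 (log2 1.75). Its ligand gene Tnfsf11 differed by 0.40 and was not called (adjusted p 0.347).

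Genes that fell outside the lists included Igfbp3 (-1.79), Meg3 (-1.34 with 1 probe set and -0.66, not called, with another) and the chemokine gene Cxcl12 (-1.56, with other probe sets at -1.40 and -0.65, the last not called). Mmp12, a macrophage elastase, rose by 1.71 and 1.05 with its probe sets, and Cyba, an oxidase subunit of phagocytes, by 1.05 and 1.27.

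A lower content of hormone-sensing luminal cell RNA was a hypothesis drawn from Cited1, Foxa1, Prom1 and Tph1 (-1.51), which had been seen to fall. A list of such genes had 7 tested members, of which these 4 fell and none rose (camera p 0.000738, and 0.0254 with an estimated correlation), but the test used the genes that prompted it. The 3 unseen members, Wnt4 (-0.44), Stc2 (-0.40) and Tnfsf11 (0.40), had a median of -0.40 and none was called by limma, so the data leave the hypothesis open.

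For the number of changed probe sets, genes and at least 2-fold genes, the 10 splits of the 6 arrays into 3 and 3 are too few to give a share under 0.05. The real split, the only 1 of the 10 with as many, gave 1586 probe sets, 1282 genes and 380 genes of at least 2-fold, and the highest of the other splits gave 0 for each in limma. At an unadjusted p under 0.05 the real split gave 2017 genes and the highest of the others 230. Each of the other splits mixes arrays of both groups, so a group difference enlarges the spread within it. Their low counts are therefore no measure of chance.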
